A study of Camellia japonica and Camellia azalea with 81 samples.

How the data were processed

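RNA sequencing of 81 libraries was deposited for 2 evergreen shrubs of the tea family. Leaves of Camellia japonica and of Camellia azalea were sampled in each of 12 months, with 3 libraries per species and month, and flower buds of C. japonica carry the labels FB-1, FB-2 and FB-3, with 3 libraries each. Per the labels' protocols, RNA was taken with a plant kit meant for tissue rich in polysaccharides and polyphenols, and Illumina libraries were made from it. The labels do not say whether the 3 libraries of a month came from separate plants, so p-values measure the spread between these samples, which may be technical. The stages and months behind FB-1 to FB-3 are not given in the sources used here. Each column was tied to its library through the code in the sample title. Replicate numbers in C. azalea come from the labels. Those in C. japonica follow the order of deposit and only name a library.

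The values deposited by the authors are TPM (transcript abundances scaled to a fixed total per library), in 1 table per species. Per the submitters' processing notes, HISAT2 2.1.0 (an aligner) and StringTie 1.3.6 (an assembler and quantifier) were used. Their settings, the genome build and the annotation are not given in the sources used here. Each deposited TPM column summed to 1000000 over 41982 gene IDs. TPM keep no depth, so the sequencing depth of each library is unknown and no counting interval or floor is given. TPM are also shares of a fixed total: where a few genes take more of it, every other gene is listed lower. A total of 41952 IDs occurred in both tables. The tables were normalized separately, so no level was compared across the species, and a difference between them was always a difference of differences taken within each table.

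The IDs are not paired with gene names in the files, and no annotation was used here. The marker and pathway lists fixed before the data were examined matched 0 IDs and were not tested. At most 2 IDs that rose and 2 that fell are therefore named per comparison. The rule, fixed before the data were examined, took the called IDs with the largest differences and a mean of at least 5 TPM in the higher group. For the month effect, the annual curve and the neighbouring months it took the 2 called IDs with the largest range of month means.

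Tests were run in R 4.3.3 with limma 3.58.1 on log2(TPM + 1), with a mean-variance trend, on genes with at least 1 TPM in at least 3 libraries of the fit. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05 and a log2 difference of at least 1. Fold changes on this scale understate the change of genes with low values. The month effect was a moderated F test over 12 month means, called on the range of those means. The annual curve was a cosine and sine of the month number with a period of 12 months, called on its height from trough to peak. Winter was the mean of the Dec, Jan and Feb means and summer that of the Jun, Jul and Aug means. The species difference was the winter minus summer difference in C. japonica minus that in C. azalea, in 1 fit of the 72 leaf libraries. Bud contrasts were fitted on the 9 bud libraries, and buds were set against leaves in 1 fit of the 45 C. japonica libraries. Overlaps were tested with Fisher's exact test over the genes tested in both comparisons.

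The procedures were tested on simulated data with the means and spreads of the real genes, where 200 genes with a mean of at least 5 TPM were changed. Values were drawn gene by gene, without shifts of whole libraries or libraries of another tissue. The false calls therefore say nothing about errors from these. For winter against summer in C. azalea, 89% of 100 genes changed by 1.5 on the log2 scale and 100% of 100 changed by 3 were recovered, with 5 false calls among 26570 genes tested. In C. japonica the shares were 86% and 99%, with 6 false calls among 29117 genes. For the month effect they were 38% and 96% in C. azalea and 40% and 80% in C. japonica, with 11 and 8 false calls. For the neighbouring months Dec to Jan was simulated in both species, and Feb to Mar was not. The shares were 47% and 97% in C. azalea and 67% and 95% in C. japonica, with 9 and 8 false calls. The annual curve had 92% and 100% in C. azalea and 86% and 99% in C. japonica, and the species difference 75% and 93%, with 3, 4 and 2 false calls. The month effect was simulated as a rise in the Jan libraries alone, and changes spread over several months were not simulated for it. Its test missed most genes with such a rise of 1.5, as did Dec to Jan in C. azalea. For FB-3 against FB-1 they were 20% and 59%, with 5 false calls among 30121 genes, for FB-2 against FB-1 26% and 49%, and for FB-3 against FB-2 21% and 61%, so the bud contrasts had less power still at a change of 3. For flower bud against leaf they were 95% and 99%, with 5 false calls among 31254 genes.

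Alternatives fixed before the data were examined were a pseudocount of 0.1 TPM, no filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, no variance trend, no size threshold, each library left out in turn, the replicate number as a block, other definitions of season and of the error, and other fits for the bud and species contrasts. A further 3 alternatives were chosen after seeing the data. They left out the library labelled Feb leaf 1 and the library labelled FB-1 1, or the 6 C. azalea libraries in which 10 IDs held over 20% of TPM, or, for Dec to Jan in C. azalea, the library labelled Dec 3 together with median-of-ratios scaling. Neighbouring-month counts under other scalings were also compared after seeing the data. Figures were drawn with matplotlib 3.10.9.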

Results

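The series compares gene expression through the year in leaves of 2 camellias, C. japonica, which flowers in winter and spring, and C. azalea, which flowers mainly in summer. It comprised 36 leaf libraries of each species and 9 flower bud libraries of C. japonica. The depth of the libraries is unknown. Between 22498 and 27370 genes reached 1 TPM in the C. japonica leaf libraries, between 18638 and 25811 in C. azalea, and between 23597 and 27805 in the buds. The 10 most abundant IDs of each library held between 6.54% and 40.4% of TPM in C. azalea and between 4.12% and 15.4% in C. japonica leaves.

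Libraries followed their month labels to different degrees in the 2 tables. In C. azalea, 30 of 36 libraries correlated best, across genes, with another library of their own month. Among the exceptions, the C. azalea library labelled Jan 1 correlated best with the library labelled Apr 1 (r = 0.948). Its mean r with its own label (0.911) was the lowest in C. azalea, and its 25811 genes at 1 TPM the most. Several values named below rest on it. In C. japonica this held for 6 of 36 leaf libraries and 5 of 9 bud libraries. The library labelled Feb leaf 1 correlated best with the library labelled FB-1 2 (r = 0.904 across genes), against a mean r of 0.663 with its own label. The library labelled FB-1 1 correlated best with the library labelled Dec leaf 2 (r = 0.975), against a mean r of 0.645 with its own label. The library labelled Jan leaf 3 correlated best with the library labelled Aug leaf 2 (r = 0.941), against a mean r of 0.864 with its own label. It held EVM0013528 at 11230 TPM, against 61.2 and 97.1 TPM in the other Jan libraries, and EVM0016475 at 0.818 TPM, against 404 and 161 TPM. Labels were kept as given. Every C. japonica month comparison and every bud comparison below rests on these labels.

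**Figure D1:**
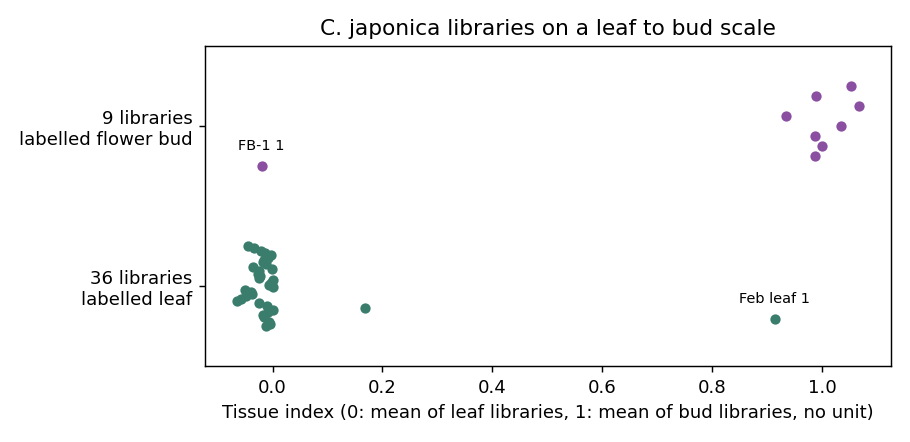
Each point is 1 C. japonica library, placed on the x axis by a tissue index without unit (0 is the mean of the leaf libraries and 1 that of the bud libraries, over 4891 IDs that differ between them), with the tissue label on the y axis. The library labelled Feb leaf 1 lies at 0.914, beside the bud libraries, and the library labelled FB-1 1 at -0.020, among the leaf libraries.

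In C. azalea leaves, EVM0033005 and EVM0016475 had the largest winter rises. EVM0033005 was at 812 ± 629 TPM in winter and 2.36 ± 3.96 TPM in summer (SD, n = 9 each), a log2 difference of 8.18 ± 0.33 (SE, limma adjusted p = 1.2e-17). EVM0016475 was at 239.5 ± 157 TPM in winter and 4.31 ± 3.31 TPM in summer, a log2 difference of 5.41 ± 0.27 (limma adjusted p = 8.3e-16). For both IDs, 9 of 9 winter libraries lay above every summer library. The summer mean of EVM0033005 was 1.09 TPM without the library labelled Aug 1. EVM0013528 and EVM0038510 had the largest summer rises. EVM0013528 was at 527 ± 888 TPM in winter and 8926 ± 2948 TPM in summer, a log2 difference of -5.32 ± 0.53 (limma adjusted p = 7.1e-09), with 9 of 9 summer libraries above every winter library. Its winter mean was 239 TPM and the log2 difference -6.07 without the library labelled Jan 1 (2834 TPM). EVM0038510 was at 35.4 ± 104 TPM in winter and 683 ± 744 TPM in summer, a log2 difference of -6.48 ± 0.93 (limma adjusted p = 4.0e-06), and 4 of 9 summer libraries lay above every winter library. Its winter mean rests on the library labelled Jan 1 (312 TPM) and was 0.782 TPM without it, as the other 8 winter libraries lay between 0.117 and 1.71 TPM. With month means as the unit, the limma adjusted p of EVM0038510 was 0.064.

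In C. japonica leaves, EVM0030864 and EVM0040544 rose most in winter. EVM0030864 was at 223 ± 200.1 TPM in winter and 0.503 ± 0.520 TPM in summer (SD, n = 9 each), a log2 difference of 5.91 ± 0.72 (SE, limma adjusted p = 2.8e-06), with 8 of 9 winter libraries above every summer library. EVM0040544 was at 254 ± 342 TPM and 1.29 ± 2.84 TPM, a log2 difference of 5.43 ± 1.1 (limma adjusted p = 0.00051). Its winter mean was 159 TPM and the log2 difference 4.74 without the library labelled Jan leaf 1 (1015 TPM), and without the library labelled Jul leaf 3 (8.80 TPM) its summer mean was 0.355 TPM. EVM0038091 and EVM0001681 rose most in summer. EVM0001681 was at 29.5 ± 29.5 TPM in winter and 1771 ± 1379 TPM in summer, a log2 difference of -5.61 ± 0.57 (limma adjusted p = 5.3e-07), with 9 of 9 summer libraries above every winter library. EVM0038091 was at 56.1 ± 128 TPM and 413 ± 156 TPM, a log2 difference of -5.79 ± 0.83 (limma adjusted p = 1.6e-05), with 386 TPM in the library labelled Jan leaf 3 and a winter mean of 14.8 TPM without it. The 4 IDs named from C. azalea had the same direction here. EVM0033005 was higher in winter by 4.95 ± 0.60 on the log2 scale (limma adjusted p = 2.8e-06), less than in C. azalea (limma adjusted p = 0.0029 for the species difference). EVM0013528 was at 1366 ± 3700 TPM in winter and 10076 ± 11238 TPM in summer, a log2 difference of -5.32 ± 0.67 (limma adjusted p = 4.3e-06). Single libraries carry these means and SDs. Without the library labelled Jan leaf 3 (11230 TPM) the winter mean was 133 TPM, and without the library labelled Aug leaf 1 (39855 TPM) the summer mean was 6354 TPM. Of the IDs named from C. japonica, EVM0030864 was not called in C. azalea (log2 difference 1.18 ± 0.58, limma adjusted p = 0.116). Its difference between the species was 4.73 (limma adjusted p = 0.0015), with the same limit as for EVM0033005. Its summer mean was 0.503 TPM in C. japonica and 0 TPM in C. azalea. EVM0038091 had similar TPM means in C. azalea, 54.3 ± 95.7 in winter (31.2 without the library labelled Jan 1 and 35.4 without the library labelled Feb 3) and 50.1 ± 18.8 in summer, with a log2 difference of -2.08 ± 0.74 (limma adjusted p = 0.030). EVM0001681 was called there with a smaller difference (-1.72 ± 0.32, limma adjusted p = 0.00016), and EVM0040544 was called as winter-high (3.02 ± 0.27, limma adjusted p = 1.2e-09). These directions held under both rescalings of the libraries that were tried for the IDs named by the rule in each species.

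**Figure D2:**
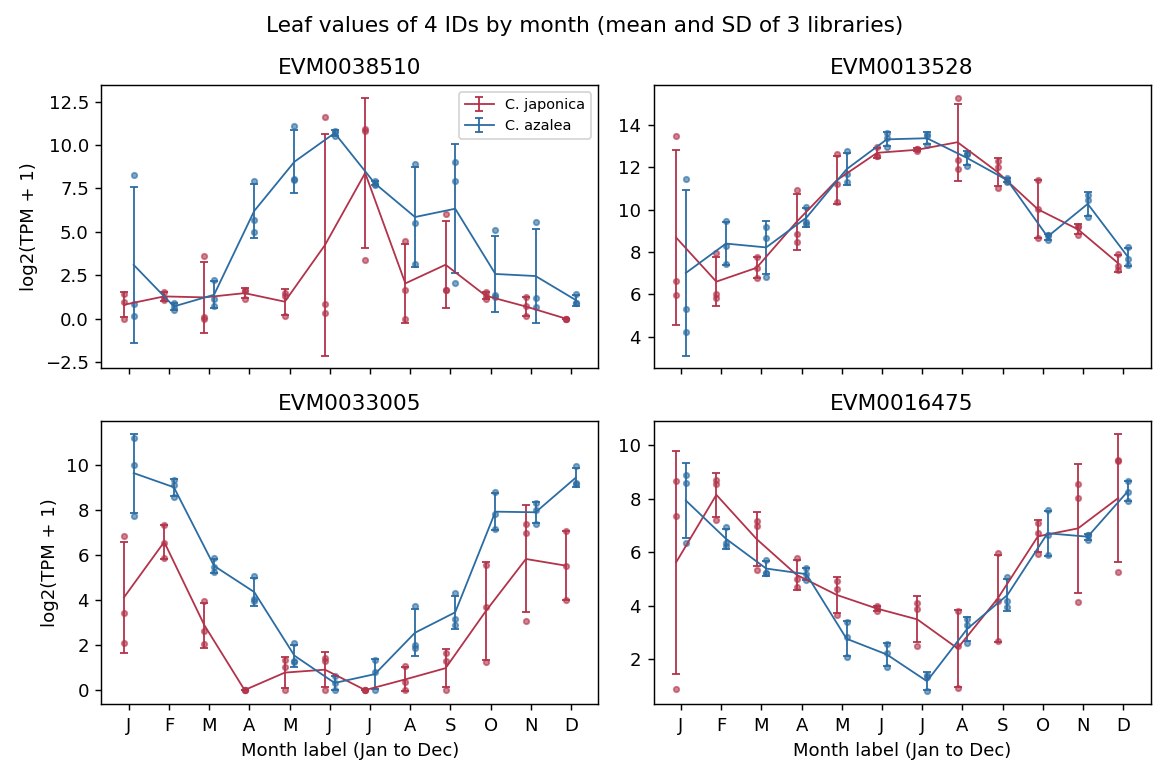
Each panel shows 1 ID, with log2(TPM + 1) on the y axis and the month label on the x axis. Points are single leaf libraries, lines join month means and bars are the SD of 3 libraries. EVM0038510 and EVM0013528 were highest in the middle of the year and EVM0033005 and EVM0016475 in winter, and the heights of the 2 species are not comparable because their tables were normalized separately.

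The number of genes that differed between winter and summer was similar in the 2 species, but which season had more of them depended on the scaling. On TPM as deposited, limma called 2518 of 29156 genes in C. japonica, 1716 higher in winter and 802 higher in summer. In C. azalea it called 2583 of 27492 genes, 1717 higher in winter and 866 higher in summer. The median log2 difference of all tested genes was itself 0.25 in C. japonica and 0.26 in C. azalea. After median-of-ratios scaling these medians were 0.01 and 0.02, and the calls became 714 winter-high and 1418 summer-high genes in C. japonica and 895 and 1403 in C. azalea. Quantile normalization gave 777 and 1217 in C. japonica and 904 and 1279 in C. azalea. With the 3 month means of each season as the unit, 544 genes were called in C. japonica and 43 in C. azalea. Without the library labelled Feb leaf 1 and the library labelled FB-1 1, C. japonica had 2942 calls, and without the library labelled Jan leaf 3 it had 3182.

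**Figure D3:**
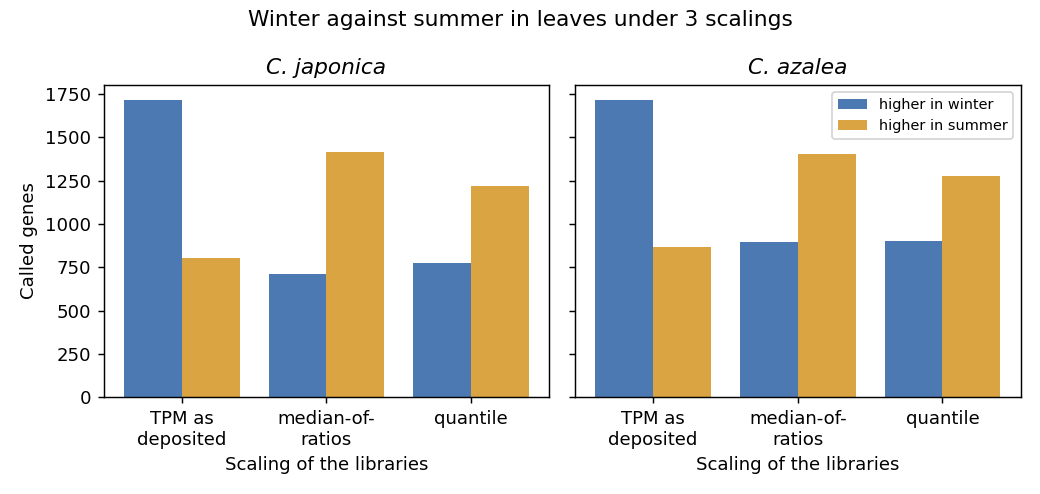
Bars are numbers of genes called by limma as higher in winter or in summer (y axis) under each scaling of the libraries (x axis), for each species. On deposited TPM winter-high genes outnumbered summer-high ones (1716 against 802 in C. japonica), and under both other scalings the order was turned (714 against 1418 and 777 against 1217).

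Genes called in 1 species were called in the other in the same season more often than for independent lists, but most were not shared. Winter-high genes tested in both numbered 1625 in C. japonica and 1620 in C. azalea, and summer-high genes 734 and 804. Of 25478 genes tested in both, 571 were winter-high in both, against 103 for independent lists (odds ratio 11.8, 95% interval 10.4 to 13.3, Fisher's exact p = 2.2e-295). Summer-high genes shared 229, against 23.2 (odds ratio 19.1, 15.9 to 22.8, Fisher's exact p = 2.2e-168). Genes high in winter in C. japonica and in summer in C. azalea numbered 21, against 51.3, and the opposite pair 9, against 46.7. Of 830 genes called in both, 800 (96.4%) had the same direction. After median-of-ratios scaling 702 of 727 did (96.6%), with odds ratios of 20.9 for winter-high and 14.8 for summer-high genes. Without the library labelled Feb leaf 1 and the library labelled FB-1 1, 791 of 859 did (92.1%). The pairs of opposite season then numbered 32, against 56.3, and 36, against 62.1. Genes are not independent replicates, so these p-values describe the lists.

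A test of the difference between the species called 1157 of 31584 genes, a count that 6 of 100 arrangements of whole months, taken alike in both species and with the real one included, reached. Relative to C. azalea, the winter minus summer difference was larger in C. japonica for 620 genes and smaller for 537. EVM0010016 moved in opposite directions: in C. japonica it was at 15.6 ± 20.5 TPM in winter and 1.89 ± 2.06 TPM in summer, and in C. azalea at 31.4 ± 34.7 TPM and 303 ± 227 TPM (SD, n = 9 each). The difference of differences was 4.80 ± 0.78 on the log2 scale (SE, limma adjusted p = 5.6e-05). EVM0011960 had a difference of 4.78 ± 1.07 (limma adjusted p = 0.0037), from 671 ± 770.1 TPM in winter and 25.7 ± 32.8 TPM in summer in C. japonica (17.04 TPM without the library labelled Jun leaf 1). EVM0036012 and EVM0041525 were summer-high in C. japonica, at 388 ± 70.4 TPM and 239 ± 41.05 TPM in summer, against 32.4 ± 58.1 TPM and 18.3 ± 31.7 TPM in winter (14.5 and 8.62 TPM without the library labelled Jan leaf 3). Their means in C. azalea lay below 1 TPM in both seasons, where little seasonal change can be measured. Their differences were -5.37 ± 0.63 (limma adjusted p = 8.7e-08) and -5.31 ± 0.57 (limma adjusted p = 5.7e-09). Without the library labelled Feb leaf 1 and the library labelled FB-1 1, 2232 genes were called. The balance then turned, with 976 larger and 1256 smaller in C. japonica.

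Over the 12 months, EVM0038510 had the widest range in C. azalea, from 0.642 ± 0.227 TPM in Feb to 1652 ± 169 TPM in Jun (SD, n = 3), a range of 9.98 on the log2 scale (limma adjusted p = 1.2e-05). EVM0002118 ranged from 5.34 ± 1.42 TPM in Sep to 4282 ± 1792 TPM in Feb (limma adjusted p = 5.1e-11). In C. japonica, EVM0036048 was at 604 ± 444 TPM in Jul and 0.129 ± 0.223 TPM in Dec (limma adjusted p = 0.039), and EVM0018910 at 4112 ± 3098 TPM and 15.9 ± 20.9 TPM in the same months (limma adjusted p = 0.036), with a Dec mean of 3.86 TPM without the library labelled Dec leaf 1. The calls of these C. japonica IDs were lost in 15 and in 8 of 36 refits that each left out 1 library, with adjusted p up to 0.167 and 0.145 without the library labelled Jul 1. The month test called 14853 of 27492 genes in C. azalea and 5111 of 29156 in C. japonica. This count fell to 3325 in C. japonica with median-of-ratios scaling and to 3122 with quantile normalization.

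An annual curve was called for 5389 genes in C. azalea and 5678 in C. japonica. EVM0038510 was named in both species, with a fitted peak at month 6.42 in C. azalea (limma adjusted p = 1.5e-06) and 6.92 in C. japonica (limma adjusted p = 0.013). The C. japonica peak rests on the libraries labelled Jun leaf 3 (3068.5 TPM), Jul leaf 1 (1811.5 TPM) and Jul leaf 2 (1973 TPM). The other 33 lay at or below 63.5 TPM, with 0.236 and 0.784 TPM in the other Jun libraries. EVM0036048 peaked at month 6.55 in C. japonica (limma adjusted p = 0.011) and EVM0002118 at month 3.61 in C. azalea (limma adjusted p = 0.0027). Of the called genes, 56.7% in C. japonica and 53.1% in C. azalea peaked in Jan to Apr on deposited TPM, and 17.72% and 20.004% in May to Aug. After median-of-ratios scaling the order turned, with 36.4% and 38.3% in Jan to Apr and 40.4% and 40.2% in May to Aug. A curve was called in both species for 1989 genes, and the peaks of 40.17% of them lay within 1 month, against 20.9% if the phases found in the 2 species were paired independently. After median-of-ratios scaling it was 35.2% against 18.8%. Among 3549 genes with a month effect in both, the median r between the monthly profiles of the species was 0.41. The highest of the 11 circular shifts of the months gave 0.40, and with 12 arrangements no p below 0.083 is possible. This was the shift of 11 months, which lies next to no shift around the year. A shift of 1 month gave 0.23, and shifts of 3, 4, 5 and 6 months gave -0.25, -0.26, -0.36 and -0.29.

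Between neighbouring months, C. azalea leaves changed most from Dec to Jan on deposited TPM, but not under every alternative. EVM0002118 rose from 7.87 ± 5.13 TPM in Dec to 481 ± 793 TPM in Jan (SD, n = 3), a log2 difference of 3.54 ± 0.84 (SE, limma adjusted p = 0.0023), with 3 of 3 Jan libraries above every Dec library. The library labelled Jan 1 (1397 TPM) carries this Jan mean: without it the mean was 22.7 TPM and the log2 difference 1.56 (adjusted p = 0.030). The Dec mean was 5.14 TPM without the library labelled Dec 1. EVM0008064 was at 1.26 ± 0.411 TPM in Dec and 109 ± 185 TPM in Jan, a log2 difference of 2.69 ± 0.93 (limma adjusted p = 0.029), which was 0.44 without the library labelled Jan 1 (adjusted p = 0.537, Jan mean 2.11 TPM) and 2.55 without the library labelled Dec 3 (adjusted p = 0.11). In all 6779 genes were called, 6322 higher and 457 lower in Jan. From Nov to Dec 4426 genes were called, 174 higher and 4252 lower in Dec. That step had 1573 calls without the library labelled Dec 3 (161 higher, 1412 lower). After median-of-ratios scaling it had 2118 (648 higher, 1470 lower). The median of all genes moved by 0.66 on the log2 scale from Dec to Jan and by 0.12 after median-of-ratios scaling, which gave 2446 higher and 1199 lower genes, and quantile normalization gave 1658 and 1314. Without the library labelled Dec 3, 3645 genes were called. Jun to Jul had fewer calls than Dec to Jan after median-of-ratios scaling (3214 against 3645) and without the library labelled Dec 3 (2568 against 3645). It had more after quantile normalization (3156 against 2972) and with median-of-ratios scaling and that library left out together (3243 against 2994), where EVM0002118 was no longer called (adjusted p = 0.074). In C. japonica the pair with most calls on deposited TPM was Feb to Mar, with 5 genes, and after median-of-ratios scaling it was Jul to Aug, with 8 against 6. EVM0009960 rose from 3.09 ± 4.12 TPM (0.716 TPM without the library labelled Feb leaf 1) to 49.7 ± 39.3 TPM (27.6 TPM without the library labelled Mar leaf 3; limma adjusted p = 0.0099) and EVM0019745 from 24.3 ± 16.04 TPM to 184 ± 2.44 TPM (limma adjusted p = 0.032). The count was 45 without the library labelled Feb leaf 1 and 0 without the library labelled Mar leaf 1, 12 of 36 refits moved it by over 1.5 times, and these 2 calls were lost in 3 and 4 of 36 refits that left out 1 library.

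**Figure D4:**
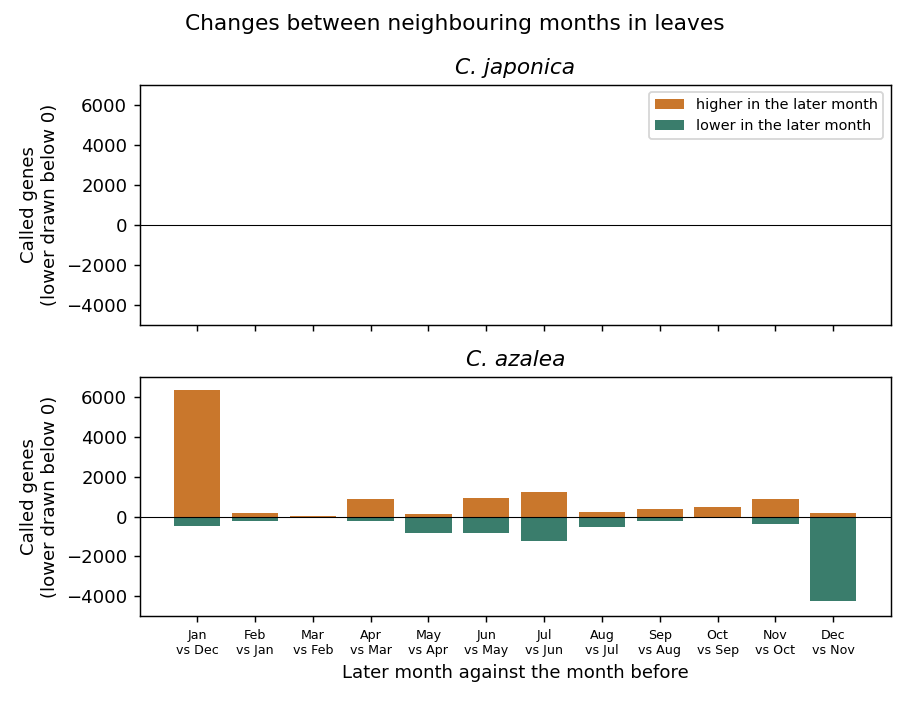
Bars are numbers of genes called by limma on deposited TPM in each month against the month before (x axis), with genes higher in the later month above 0 and lower ones below. C. azalea shows 6322 higher genes in Jan and 4252 lower genes in Dec. Without the library labelled Dec 3 these were 3206 and 1412. C. japonica has at most 5 calls at any step, too few to be seen on this scale.

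Among the buds, EVM0016378 and EVM0029049 rose most from FB-1. EVM0016378 was at 0.999 ± 1.73 TPM in FB-1, 6606 ± 916 TPM in FB-2 and 4433 ± 1122 TPM in FB-3 (SD, n = 3 each), with log2 differences of 12.01 ± 0.52 (SE, limma adjusted p = 9.7e-06) and 11.41 ± 0.52 (limma adjusted p = 1.5e-05). EVM0029049 was at 0.900 ± 1.56 TPM, 4819 ± 647 TPM and 3949 ± 975 TPM. For both IDs the FB-1 mean comes from the library labelled FB-1 3 alone, and the other 2 were at 0 TPM. EVM0016618 fell from 33.5 ± 7.28 TPM in FB-1 to 2.02 ± 1.17 TPM in FB-2 (limma adjusted p = 0.0059), and EVM0040189 from 167 ± 109 TPM to 13.4 ± 1.68 TPM (limma adjusted p = 0.023). EVM0004539 fell from 78.1 ± 41.1 TPM in FB-1 to 1.497 ± 1.45 TPM in FB-3 (limma adjusted p = 0.017), and EVM0013617 from 1173 ± 1751 TPM to 1.81 ± 1.13 TPM (limma adjusted p = 0.034). The FB-1 mean of EVM0013617 was 163 TPM without the library labelled FB-1 3 (3193.5 TPM), and its log2 difference changed from -7.27 to -5.78. The FB-1 mean of EVM0040189 was 107 TPM without the library labelled FB-1 2, and the FB-3 mean of EVM0004539 was 0.794 TPM without the library labelled FB-3 2. The calls of EVM0040189 and EVM0013617 were each lost in 6 of 9 refits that left out 1 library, and that of EVM0004539 in 3 of 9, with adjusted p up to 0.116, 0.13 and 0.068.

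Limma called 183 of 29394 genes between FB-2 and FB-1, 179 higher and 4 lower in FB-2, and 594 between FB-3 and FB-1, 410 higher and 184 lower in FB-3. Between FB-3 and FB-2 limma called 0 genes, with 3005 at an unadjusted p below 0.05. These counts depended on the library labelled FB-1 1, which resembled leaves. Without it and the library labelled Feb leaf 1, the counts were 499 (276 higher, 223 lower), 4306 (1397 higher, 2909 lower) and, for FB-3 against FB-2, 380 (97 higher, 283 lower). With all 45 C. japonica libraries in the fit they were 1229, 3838 and 1189. Leaving out single libraries took the count for FB-3 against FB-1 from 113 (without the library labelled FB-3 1) to 4306, and 8 of 9 such refits moved it by over 1.5 times.

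Flower buds differed from leaves in 11105 of 32406 genes. EVM0004459 was at 1126 ± 819 TPM in the 9 bud libraries and 3.50 ± 14.2 TPM in the 36 leaf libraries, a log2 difference of 7.67 ± 0.56 (SE, limma adjusted p = 1.9e-13), and EVM0002293 was at 2177 ± 1014 TPM and 77.1 ± 382 TPM (limma adjusted p = 6.5e-09). EVM0016462 was higher in leaves, at 3203 ± 1388 TPM against 160 ± 454 TPM in buds (limma adjusted p = 3.2e-13), with 33 of 36 leaf libraries above every bud library. EVM0025169 was at 341 ± 286 TPM in leaves and 7.18 ± 21.5 TPM in buds (limma adjusted p = 8.9e-14). The low mean of each of these 4 IDs rests on 1 of the 2 libraries that resembled the other tissue. The leaf means of EVM0004459 and EVM0002293 were 1.15 and 14.2 TPM without the library labelled Feb leaf 1 (85.9 and 2277 TPM). The bud means of EVM0016462 and EVM0025169 were 8.44 and 0 TPM without the library labelled FB-1 1 (1369 and 64.6 TPM). On deposited TPM 7898 genes were higher in buds and 3207 in leaves, with a median over all genes of 0.41 on the log2 scale. The split was 6294 to 3790 after median-of-ratios scaling and 4765 to 4830 after quantile normalization, with medians of 0.22 and 0.02.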

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

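The test of the difference between the species singled out 1157 genes whose winter minus summer difference was not the same in C. japonica and C. azalea. The 2 largest in each direction were EVM0010016 (4.80 on the log2 scale, C. japonica minus C. azalea) and EVM0011960 (4.78), and EVM0036012 (-5.37) and EVM0041525 (-5.31). In C. azalea alone EVM0010016 was higher in summer (log2 difference -3.12, limma adjusted p = 7.1e-06), while in C. japonica it was higher in winter (1.68, limma adjusted p = 0.030). EVM0011960 was higher in winter in C. japonica (3.48, limma adjusted p = 0.0033), and its difference in C. azalea missed the threshold (-1.30, limma adjusted p = 0.072). Among arrangements of whole months, the real one included, 6 of 100 gave as many genes with the same months taken in both species and 29 of 100 with months drawn separately, so a chance arrangement of months was not excluded for this count. Groups of 3 libraries were searched for single outlying values only for the named IDs, by leaving out each library in turn, and not over all genes.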

How the results depend on the processing

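A total of 99 values of the 14 main results stayed within 1.5 times the main count, or within the spread, under the alternatives other than single left-out libraries, and 34 moved further. No named ID changed sign, but the balance of directions turned: under median-of-ratios scaling and quantile normalization summer-high calls outnumbered winter-high calls in both species (714 against 1418 winter-high to summer-high in C. japonica and 895 against 1403 in C. azalea after median-of-ratios scaling), and after quantile normalization bud-high genes were slightly fewer than leaf-high ones (4765 and 4830). Of the values for named IDs, 333 kept direction and call and 14 lost the call with the direction kept. The cause was not tested unless named. Depth is unknown and limits all low values.

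Fewer genes were tested with a mean of at least 5 TPM, which gave 9835 genes for the month effect, 3379 for the annual curve and 4183 for Dec to Jan in C. azalea, 667 for the species difference, 6778 for bud against leaf and 1 for Feb to Mar in C. japonica. Without a size threshold the annual curve had 12725 genes in C. japonica and 10011 in C. azalea, winter against summer 8632 and 9118, and bud against leaf 21880. With a pseudocount of 0.1 TPM winter against summer in C. azalea had 4466 genes and Feb to Mar in C. japonica 1. Feb to Mar had 16 genes without a filter and 11 without a variance trend. Median-of-ratios scaling gave 3325 genes for the C. japonica month effect and 3645 for Dec to Jan. Quantile normalization gave 3122 and 2972, and 1 for FB-3 against FB-2. With month means as the unit winter against summer had 544 genes in C. japonica and 43 in C. azalea, and Nov to Jan against May to Jul had 1628 in C. japonica. Fitted with all 45 libraries FB-2 against FB-1 had 1229, FB-3 against FB-2 1189 and FB-3 against FB-1 3838 genes. The median profile r was 0.29 over all genes tested in both species.

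Chosen after seeing the data, leaving out the library labelled Feb leaf 1 and the library labelled FB-1 1 gave 45 genes for Feb to Mar, 2232 for the species difference, 499 for FB-2 against FB-1, 380 for FB-3 against FB-2 and 4306 for FB-3 against FB-1. The balance of directions then turned for the species difference (976 larger, 1256 smaller) and for FB-3 against FB-1 (1397 higher, 2909 lower). Leaving out the 6 C. azalea libraries with 10 IDs above 20% of TPM gave 4518 genes for Dec to Jan. Median-of-ratios scaling together with leaving out the library labelled Dec 3 gave 2994.

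With single libraries left out, Feb to Mar in C. japonica ranged from 0 to 45 genes, the species difference from 942 to 2232 (highest without the library labelled Feb leaf 1), FB-2 against FB-1 from 82 to 499, FB-3 against FB-2 from 0 to 380 and FB-3 against FB-1 from 113 to 4306 (each highest without the library labelled FB-1 1), and Dec to Jan in C. azalea from 3645 (without the library labelled Dec 3) to 8346.

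With the replicate number as a block in C. azalea the month effect had 14331 genes, the annual curve 5298, winter against summer 2579, Dec to Jan 6665 and the species difference 1108, each within 1.5 times the main count. Same-numbered libraries of different months deviated together with a mean r of -0.021, and 4 of 36 libraries matched their own number best. The replicate number thus marked no common deviation. As r of single pairs ran from -0.64 to 0.56, a weak effect of shared plants could go unseen and is not excluded.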

Other observations

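Of the tests in this part, those on the 2 libraries that resemble the other tissue, on column order, on abundant IDs in C. japonica libraries, on bud-high IDs in C. azalea and on months arranged alike in both species were chosen after the result was seen.

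Genes higher in C. japonica buds than leaves overlapped with genes higher in winter than summer in C. azalea leaves. Of 26337 genes tested in both, 824 were in both lists, against 359.66 for independent lists (odds ratio 3.97, 95% interval 3.58 to 4.40). Leaf-high genes overlapped with summer-high C. azalea genes, 413 against 94.1 (odds ratio 8.96). After median-of-ratios scaling the odds ratios were 5.09 and 8.15. The libraries compared were independent, and genes are not independent replicates.

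The library labelled Feb leaf 1 and the library labelled FB-1 1 resembled the other tissue. The library labelled FB-1 1 lay at -0.020 on the leaf to bud scale, within the range of the other leaf libraries (up to 0.169). Its bud-high IDs were at a median of 0% of the bud mean, below the highest leaf library (9.23%). Both upper limits come from the library labelled Mar leaf 3, which itself lay somewhat towards the buds. Apart from it and the library labelled Feb leaf 1, leaf libraries lay at or below 0 and 1.19%. The values of the library labelled FB-1 1 argue against a share of bud RNA and lie among those of leaf libraries. The library labelled Feb leaf 1 lay at 0.914, just under the lowest of the other 8 bud libraries (0.935), so the bound set for a bud library was missed narrowly. Its leaf-high IDs were at 7.35% of the leaf mean, below the highest bud library (7.75%), which argues against a large share of leaf RNA. Its bud-high IDs were at 53.1% of the bud mean, below the lowest of the other 8 bud libraries (65.6%). The IDs of both measures were chosen with those 8 libraries, and the bud mean includes them. A bud library outside them may therefore score lower, so neither shortfall counts against a bud library. What this library is stays open. A swap of the 2 libraries or a bud of a stage not otherwise sampled may explain it, and the latter was not tested. In a plain swap the library labelled FB-1 1 would be a Feb leaf library. It correlated best with the library labelled Dec leaf 2 (r = 0.975). Its top ID was EVM0025230, as in the Dec leaf libraries, against EVM0005515 in the remaining Feb leaf libraries. The mean r was 0.978 in columns 35 to 37, which end with it, against 0.933 in the Dec-labelled columns 34 to 36. These values argue against a plain swap. They do not exclude it, as leaf libraries often matched other months best.

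From Dec to Jan in C. azalea leaves 6779 genes were called, mostly higher in Jan. Median-of-ratios scaling, which allows for a few abundant IDs taking up TPM, gave 3645 genes (2446 higher, 1199 lower), of which 2887 were among the 6779, and this was under the bound set beforehand. Leaving out the library labelled Dec 3, where 10 IDs held 40.4% of TPM, gave 3645 genes as well, by coincidence the same number but with another split (3206 higher, 439 lower). With both together, an alternative chosen after seeing each alone, 2994 genes were called (2085 higher, 909 lower), 2406 of them among the 6779, so both technical explanations may account for part of the step, and the cause of the rest stays open. After scaling, IDs high in C. japonica buds were over-represented among those higher in Jan (odds ratio 8.94), so a change in young or bud tissue among the sampled leaves stays open, beside the season itself, which was not tested apart.

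C. japonica leaf libraries resembled libraries of other months more than those of their own. If columns 9 to 20 were shifted against the labels by 1 column, the shifted groups of 3 neighbouring columns would have the higher mean r in each of 4 months; they did in 3 (May 0.966 to 0.984, Jun 0.956 to 0.974, Jul 0.933 to 0.981), and the opposite gap in Apr (0.959 to 0.952) was smaller than the SD between groups (0.014), so a shift there stays open. In columns 21 to 34 the better of the shifts tried exceeded the labelled groups by 0.013 (mean r 0.927 against 0.914). This was above the bound of 0.01 first set but below the SD of the shifted groups (0.016). The comparison with the SD, in both sets of columns, was added after these values were seen, so a shift stays open here too. It is not the shift of columns 9 to 20, where the shifted groups started 1 column earlier than the labels. In columns 21 to 34 the better groups started 1 column later, or 2 earlier. Groups starting 1 column earlier had a mean r of 0.913 there, no higher than the labelled groups. The share of TPM in the 10 most abundant IDs did not go with a lower r within the label (Spearman rho = 0.16, permutation p = 0.36, Pearson r = 0.34, permutation p = 0.056, n = 36, adjusted p = 0.36 and 0.11 over these 2 tests, and r = 0.39 without the 2 libraries farthest from the median). Real differences between plants or sampling days may also produce this pattern and were not tested.

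Other splits of the samples were counted for each result, with the real split included among them. In 1 of 100 splits, the real one, were there as many genes as with the labels for 8 results, so a chance assignment of single libraries was excluded at a share of 0.05. These were the month effect in C. japonica (5111 genes, highest other split 506) and C. azalea (14853, 5077), the annual curve (5678, 459 and 5389, 1394), winter against summer (2518, 149 and 2583, 709), the species difference (1157, 9) and bud against leaf (11105, 8). With 3 against 3 libraries only 10 splits exist, too few for a share under 0.05. The real split gave 183 genes for FB-2 against FB-1 (highest other 140), 594 for FB-3 against FB-1 (11) and 6779 for Dec to Jan in C. azalea (166), each matched by 1 of 10 splits. For FB-3 against FB-2 all 10 splits gave at least the 0 genes of the real one, and the highest other gave 47. For Feb to Mar in C. japonica 5 of 10 splits gave at least the 5 genes of the real one, and a split that put the library labelled Feb leaf 1 with the libraries labelled Mar leaf 1 and Mar leaf 3 gave 999, which points to a structure of these libraries other than the month labels.

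Single libraries shuffled over the year ignore that the libraries of a month go together, so the months were also rearranged as whole groups of 3 libraries. Of 100 arrangements, the real one included, 1 gave as many genes as the labels for the annual curve in C. japonica (5678 genes, highest other 1857) and 1 in C. azalea (5389, 4049). For winter against summer it was 1 in C. japonica (2518, highest other 1869) and 2 in C. azalea (2583, 2975), so a chance arrangement of months was excluded for these 4 counts at a share of 0.05. It was not excluded for the species difference: 29 of 100 arrangements drawn separately in each species gave at least its 1157 genes (highest other 6296), and so did 6 of 100 with the same months taken in both species (highest other 2703). With month means as the unit the winter against summer counts were 544 in C. japonica and 43 in C. azalea, so most calls of single genes rest on the spread within months.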
